A study of Danio rerio with 2 samples.

How the data were processed

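Single blood cells of zebrafish larvae at 5 dpf were measured by MARS-seq 2.0, a plate method that reads the 3' ends of polyadenylated RNA and counts unique molecular identifiers (UMIs) per gene and well. Per the labels, some cells descended from endothelial cells photoconverted at 2 dpf in the Tg(kdrl:nls-kikume) line, and the others came from a runx1 reporter line or from a cross of cd41 and gata2b reporter lines. Pools of whole or dissected larvae were dissociated, and live single events were sorted into 28 plates of 384 wells, in 2 sessions of 14 plates, per the labels. The 2 sessions are the 2 deposited samples and are replicates 1 and 2 of 1 group.

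The deposited values are raw UMI counts per gene row and well, with no normalization. Reads were converted with bcl2fastq 2.20.0, per the submitters' processing notes, and were mapped to the curated Lawson Lab annotation with the scripts of the MARS-seq pipeline, per the labels. Each session holds 28 batches of 192 wells, and a batch is a pool of wells amplified together under 1 pool barcode. The count tables list 38847 gene rows and 92 spike-in rows for 10752 wells. A further limit is that 3253 gene rows carry several IDs whose reads were not told apart, and these rows hold 1.31% of gene molecules.

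The gene rows carry only annotation IDs, which the files do not pair with gene names, and 0 of 36351 IDs matched the reference name tables used here. Gene symbols, cell type markers, gene lists and mitochondrial genes were therefore not used, clusters are given by number, and at most 2 higher and 2 lower IDs are printed. Comparisons of named cell classes and of gene lists that had been planned before the data were examined were not made. The plate tables give a population and a number of cells per well, and a date of capture plates per batch. This date was taken as the sorting date, which its header does not state. Population names (AGM, AKT, KT, CHT, ant, trunk, he-ant, canonical and non-canonical) are used as the tables give them, with spellings of canonical and non-canonical merged. The labels do not say which of these corresponds to EHT pol+ or EHT pol-.

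A well was kept with 1 sorted cell, at least 500 gene molecules and at least 200 genes, spike-ins left out. Wells that the plate tables list with 0 cells were the background, measured the same way. No doublet caller was run, since single events were sorted through a singlet gate per the labels. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and levels of single sums carry exact Poisson intervals. Both cover counting error only.

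For clustering, each molecule was drawn to a clustering part with probability 0.7. This part was scaled to 10000 per cell and log transformed, 2000 variable genes were picked within sessions, each gene was standardised within session, and 30 principal components, 15 nearest neighbours and Leiden resolution 1 were used (scanpy 1.11.5, igraph 0.11.9). Exact neighbours and rounded components replaced an approximate search so that the clusters repeat on another machine. This replacement was made after shares per population had been seen and changed the number of clusters.

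Counts were summed per session and population for the planned comparison of canonical with non-canonical cells, the only conditions that both sessions hold. They were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM, filterByExpr, session as a block, false discovery rate 0.05). All other tests were designed after the files were seen. In these, sums per sorting day with at least 8 cells a side, with day as a block and without the richest 1% of kept wells of each session (57 wells), were tested in the same way. Larvae were 5 dpf at each sort, so different dates are different larvae if the dates are those of sorting. The tables name no animals, and p-values measure the spread between days or sessions, except in the fits within clusters, where several sums of a day entered. The populations of a day were taken to come from larvae sorted that day, which is where the pairing comes from. On days 1, 3, 6 and 7 of session 1 the CHT side and the other side lay in different batches. The day block cannot separate region from batch there. Shares per day were compared with exact two-sided sign-flip permutation tests, adjusted by the Benjamini-Hochberg method over 19 clusters, or in other clusterings over the numbers that held cells. The pairs of clusters 2 and 5 and of clusters 3 and 4 were picked after their shares were seen.

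Populations within 1 session were also compared without a test by a rule of size fixed before the data were examined. A gene needed at least 30 UMIs over both sums, Poisson intervals that did not overlap, and the same direction in every pair of plates with at least 10 cells. Ratios add 0.5 UMI. Named genes were to be those past the threshold with the largest changes, the same direction in both sessions and at least 50 CPM in the higher side, of which the first 2 in each direction are printed.

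Wells of different batches in a session carry the same set of cell barcodes. Each well was correlated over 3000 genes with richer wells of the same barcode in the other batches after removal of batch means, and was called alike above a correlation of 0.3. The same was done with barcodes shuffled over all wells of a batch, across populations and wells with no cell, so the shuffled share does not keep the plate layout. A batch was past the limit when the share alike exceeded the shuffled share by 20 percentage points or more. Both limits were set after the shares per batch were seen.

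The edgeR fits of canonical and CHT sums, the rule of size and the search for shared barcodes were tested on simulated data, while the clustering, the tests of shares, the fits within clusters and the comparisons of 2 days were not. For canonical sums per session, 5.56% of genes changed by a log2 of 1 and 65.5% of those changed by 2 were recovered among 6266 genes. For canonical sums per day the shares were 50% and 100% among 1228 genes, and for CHT sums per day 55.1% and 100% among 7707 genes. The edgeR simulations drew negative binomial counts at the fitted dispersion. They held no differences between days or sessions and left out the quasi-likelihood spread, so recovery in the data may be lower. The rule of size recovered 77.5% of 200 genes changed by a log2 of 2 and also called 53 unchanged genes among 5405. That simulation drew Poisson counts for 2 plates a side, with no spread between cells, plates or days, so false calls in the data may be more frequent. For shared barcodes, only session 2 was simulated, with barcodes first shuffled within batch and population. A batch given molecules of another stood 84.2 points above the shuffled share, and 0 other batches passed the limit.

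Alternatives were another UMI minimum (300 or 1000), other Leiden resolutions (0.6 and 1.5), another standardisation, clustering without the genes that differed between regions within clusters, without all genes that differed between regions or without those of a single ID among them, DESeq2 1.42.0 and its size factors, no filter on low counts, no block (also on the genes of the blocked test), thinning of each cell to 1000 UMIs (which left out 1020 kept cells), and leaving out the richest wells, batches past the barcode limit, clusters closest to wells with no cell, a plate of session 2 whose layout repeated another's, or each sorting day.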

Results

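The data comprised 10752 wells, of which 5543 held 1 sorted blood cell that passed the limits. Session 1 contributed 3306 cells of 9 sorting days and 15116701 gene molecules. Its populations were AKT (1471 cells), CHT (673), KT (409), AGM (205), CD41_Gata2b_AKT (188), CD41_Gata2b_CHT (174), canonical (142) and non-canonical (44). Session 2 contributed 2237 cells of 8 sorting days and 8783433 molecules, from runx1-ant (832 cells), canonical (341), runx1-cht (335), runx1-trunk (309), he-ant (278) and non-canonical (142) populations. The median cell held 3101 UMIs in session 1 and 1854 in session 2. The richest 1% of kept wells held 18.4% of all kept molecules.

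In session 1, 85.1% of single-cell wells were kept (95% interval 84 to 86.2), against 50.7% (49.2 to 52.2) in session 2. Among wells listed with 0 cells, 246 of 1492 (16.5%) in session 1 and 140 of 961 (14.6%) in session 2 passed the same limits. Wells were also compared by cell barcode. Of the kept wells, 18.6% in session 1 and 31.5% in session 2 resembled a richer well of the same barcode in another batch, against 9.32% and 16.7% with barcodes shuffled. There were 12 batches past the limit, with 803 kept wells. The shuffling crossed populations and wells with no cell, so the excess over it can also hold plate layout. In simulated session 2 wells that kept the positions of populations, 0 batches without added molecules passed the limit. Session 1 was not simulated.

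**Figure D1:**
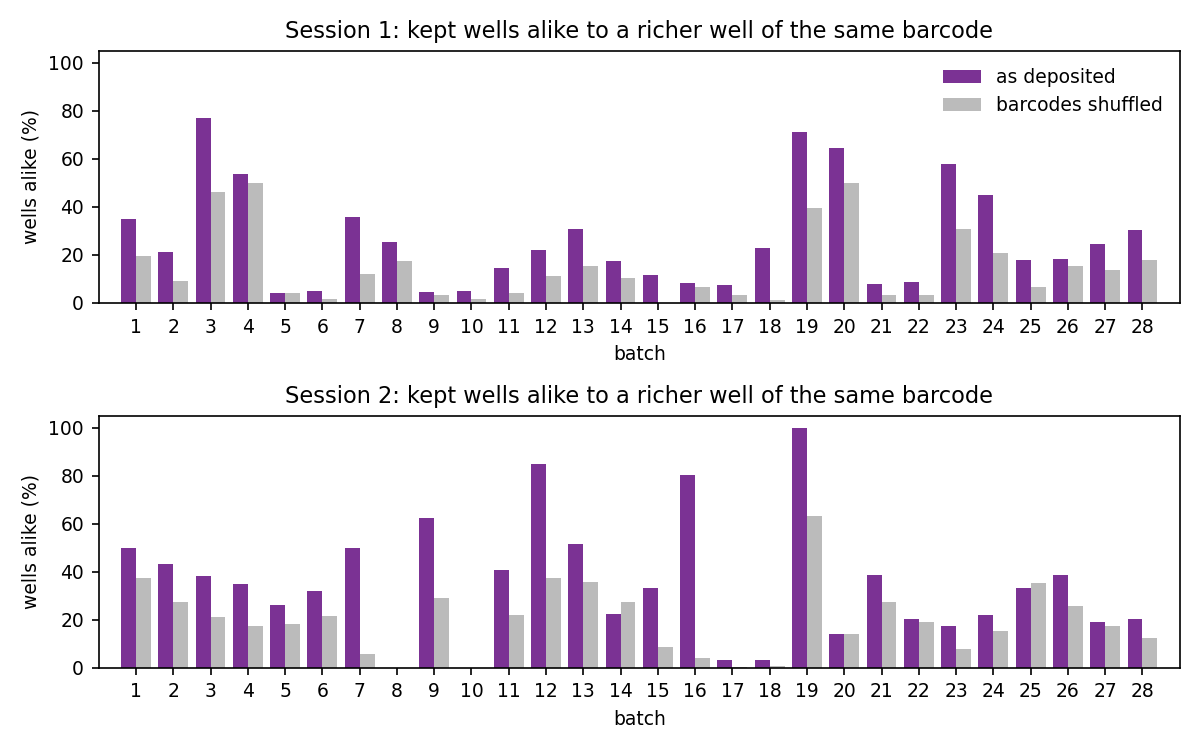
Percent of kept wells of each batch (y axis) that resembled a richer well of the same cell barcode in another batch, as deposited and with barcodes shuffled, for the batches of each session (x axis). In session 2, batch 16 stood at 80.4% against 4.29% shuffled and batch 19 at 100% against 63.4%.

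The first question was whether cells from the CHT differed in kind from cells of the other regions. Clustering gave 19 clusters. Clusters 2 and 5 held 65.7% of CHT cells (62 to 69.3), 65.5% of CD41_Gata2b_CHT cells (57.9 to 72.5) and 62.7% of runx1-cht cells (57.3 to 67.9), with intervals that cover counting error only. Sorting days differed, and the 6 days of CHT cells had 84.9% on day 3 and 69.7% on day 2 but 26.9%, 36.7%, 28.3% and 32.7% on the others. Among session 1 batches with CHT cells, 3, 7, 19, 23 and 24 were past the barcode limit. Of their kept wells, 76.9%, 35.7%, 71.1%, 57.7% and 44.8% resembled a richer well of the same barcode (46.2%, 11.9%, 39.5%, 30.8% and 20.7% shuffled). In CHT batch 4, 90 of 163 wells with no cell passed the limits of kept wells. Clusters 2 and 5 held 4.35% of AKT, 4.89% of KT, 2.66% of CD41_Gata2b_AKT and 7.57% of runx1-ant cells. Shares were higher in AGM (11.7%, 7.65 to 16.9) and he-ant cells (20.9%, 16.2 to 26.1). In batch 17, which held AGM and KT cells, 21.2% of 146 cells fell in these clusters. Batches 18, 21 and 22 of the same populations had 2.48%, 2.01% and 2.74%. Batch 17 was not past the barcode limit (7.53% alike, 3.42% shuffled). Its wells correlated with same-barcode wells of CHT batch 11 by 0.1187 more than with others, the median over pairs of batches being 0.0246. Of the 58 he-ant cells in these clusters, 30 came from batch 19, where they were 73.2% of 41 cells. In that batch 100% of wells resembled a richer well of the same barcode (63.4% shuffled), most closely in runx1-cht batch 14. In batch 20, also he-ant, 8.45% of 71 cells fell in these clusters. Canonical and non-canonical cells had 14.1% and 22.7% in session 1, and 8.21% and 5.63% in session 2. Clusters 3 and 4 had the opposite distribution, with 51.3% of KT, 39.8% of runx1-ant, 38.3% of AKT and 14.4% of CD41_Gata2b_AKT cells, against 1.19%, 1.15% and 1.79% in the CHT populations. The runx1-trunk cells had 38.8% (33.4 to 44.5) in clusters 2 and 5 and 11% in clusters 3 and 4. Of their wells in batch 12, 84.7% resembled a richer well of the same barcode (37.3% shuffled), mostly in runx1-cht batch 14, and without the batches past the barcode limit runx1-trunk had 37.6% in clusters 2 and 5.

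**Figure D2:**
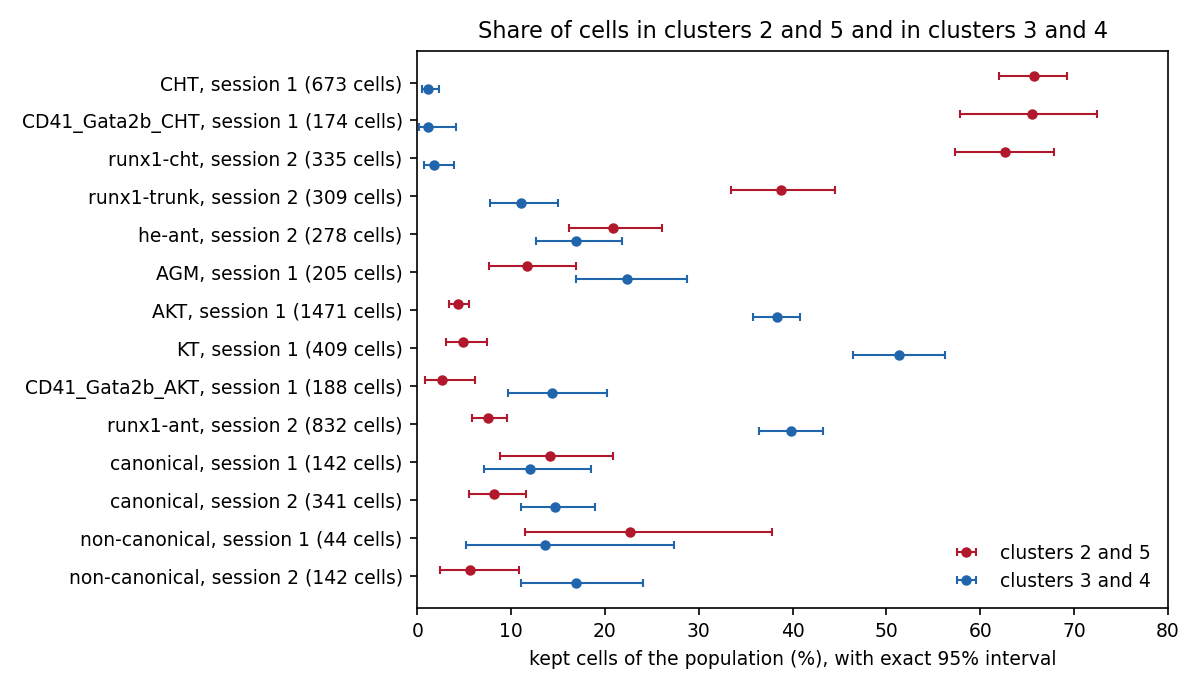
Percent of the kept cells of each population (x axis) that fell in clusters 2 and 5 or in clusters 3 and 4, with exact 95% intervals, by population and session (y axis). The 3 CHT populations lie between 62.7% and 65.7% for clusters 2 and 5.

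The difference held within sorting days, but on days 1, 3, 6 and 7 of session 1 the 2 sides lay in different batches. Region and batch cannot be told apart on those days. On days 5, 8 and 9 of session 1 the sides shared their batches. Clusters 2 and 5 then held 36.7%, 67.1% and 64.3% of CHT cells, against 2.8%, 1.24% and 3.74% on the other side. The remaining days shared part of their batches. Over 9 days with both sides, clusters 2 and 5 held 53.1% ± 21.8 of CHT cells and 4.98% ± 3.74 of the AKT, KT, CD41_Gata2b_AKT or runx1-ant cells of the day (mean ± SD, n = 9). They were higher in CHT on 9 of 9 days (exact permutation test, two-sided p = 0.00391, the smallest the design allows). Clusters 3 and 4 held 1.87% ± 1.45 against 36.8% ± 14.4 and were lower on 9 of 9 days (exact permutation test, two-sided p = 0.00391). Tested one by one, 9 of 19 clusters differed after adjustment (exact permutation tests, n = 9), with clusters 2 and 5 higher in CHT and 7 lower. With the same clusters but without the batches past the barcode limit, 8 days remained. Then 7 of 19 clusters differed after adjustment (exact permutation tests, n = 8), 2 higher in CHT and 5 lower. The call of cluster 5 depended on the standardisation. With genes standardised over both sessions together, cluster 5 held 2.51% ± 3.69 against 0.772% ± 1.4 (exact permutation test, adjusted p = 0.2, n = 9). Cluster 1 then held 38.1% ± 15.7 against 13.1% ± 6.48 (exact permutation test, adjusted p = 0.0179, n = 9). Cells were clustered again without the 553 genes that differed between the sides within clusters, and each new cluster took the number with which it shared most cells. None took number 5, and cluster 2 alone held 37.6% ± 21 against 3.09% ± 1.8, higher on 9 of 9 days (exact permutation test, two-sided p = 0.00391, n = 9). Without all 3129 genes that differed between the sides, only 38.7% of cells fell in the cluster of the same number. Again none took number 5, and cluster 2 held 29% ± 17.8 against 13.2% ± 13.5, higher on 9 of 9 days (exact permutation test, two-sided p = 0.00391, n = 9). The difference in clusters 3 and 4 did not pass, at 26.2% ± 6.93 against 33.9% ± 14.1 (exact permutation test, two-sided p = 0.125, n = 9), and of the 12 numbers that held cells 2 differed after adjustment. With the genes of several IDs put back, which left out 3079, the p for cluster 2 was 0.0234 (exact permutation test, n = 9, higher on 8 of 9 days), and of the 14 numbers that held cells 0 differed after adjustment (smallest adjusted p 0.0547). Median UMIs per cell were also higher in CHT on 9 of 9 days, by a log2 ratio of 0.83 ± 0.56 (exact permutation test, two-sided p = 0.00391, n = 9).

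**Figure D3:**
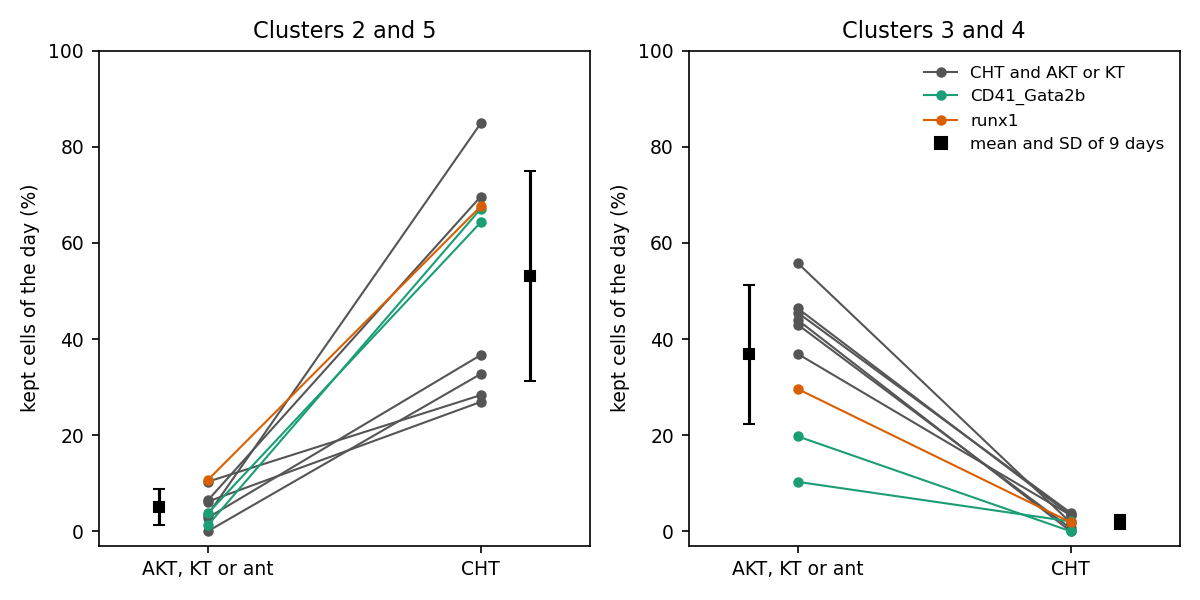
Percent of the kept cells of a sorting day (y axis) in clusters 2 and 5 (left) and in clusters 3 and 4 (right), for the AKT, KT or ant side and the CHT side of the day (x axis). Each line joins the 2 sides of 1 of 9 days, colours mark the groups of populations, and squares with bars are means and SD.

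Expression differed along with this distribution, and the days whose sides lay in different batches are among those summed here. In sums per day, 3129 of 8585 genes differed between CHT and the other side (edgeR), of which 1329 were higher in CHT and 1800 lower. Of the genes that differed, 344 were higher in CHT and 982 lower on each of the 9 days. Gene LL0000040426 was higher in CHT by a log2 of 3.77 (SE 0.593, edgeR adjusted p = 9.37e-05), with a mean of 2939 CPM against 243.7, and was higher on 8 of 9 days. Gene LL0000011951 was higher by 3.16 (SE 0.446, edgeR adjusted p = 3.25e-05), at 3747 against 400.8 CPM, on 9 of 9 days. Gene LL0000007394 was lower, with a log2 change of -4.49 (SE 0.476, edgeR adjusted p = 9.02e-08), at 1.74 against 51.54 CPM, and was higher in CHT on 0 of 9 days. The rule also named LL0000027897, with a log2 change of -5.74 (SE 0.889, edgeR adjusted p = 0.000303), which rested on the CD41_Gata2b and runx1 days. In CD41_Gata2b_AKT it had 422.3 ± 226.8 CPM over 2 days, from 3.21% of cells, while in the AKT and KT populations it had 1.273 against 4.012 in CHT, and DESeq2 gave -1.14 with an adjusted p of 0.735. When each cell was thinned to 1000 UMIs, 788 of 2970 genes differed, 260 higher and 528 lower. With no day block the count was 1946 of 5503 genes under the filter of that design, and 3048 on the same 8585 genes.

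The groups of populations were then compared. Taken alone, the CHT against AKT or KT days gave 2001 genes, the 2 CD41_Gata2b days 766 and the runx1 days 1167 (edgeR). The runx1 days, 2 of cht and 3 of ant cells, were fitted without a day block, since only 1 day held both. Over 4437 genes, log2 changes of the first group correlated with those of CD41_Gata2b at a Spearman rho of 0.716 and with those of runx1 at 0.766. These are correlations across genes, which are not independent replicates. Of 519 genes higher in CHT in the first group, 453 had a log2 change above 0 in both other groups, and of 673 lower genes, 648 had one below 0 in both. Past the edgeR threshold in the same direction were 144 of the 519 in CD41_Gata2b and 209 in runx1, and 397 and 427 of the 673. A test of the difference between the CD41_Gata2b and the first group gave 1 gene of 8495 (699 at an unadjusted p under 0.05). Within clusters, which hold the cell distribution fixed as far as the clusters resolve it, 553 of 5941 genes differed between the sides over 5 clusters, 309 higher in CHT and 244 lower. The sums were made per day, cluster and side (126 sums). Those of 1 day share larvae and entered separately, so the spread is not only that between days. Of the 553 genes, 437 had also differed in the same direction over all cells.

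Other populations were compared on the 2 days that held both sides of each comparison, with day as a block and 1 residual degree of freedom. Between runx1-trunk and runx1-ant, 479 of 3962 genes differed, 210 higher in trunk and 269 lower, and 191 with no day block. Between runx1-trunk and runx1-cht, edgeR called 0 of 5259 genes, with 270 at an unadjusted p under 0.05, and 0 with 170 without the batches past the barcode limit. Between he-ant and runx1-ant, 28 of 4869 genes differed, 58 with no day block, and no fit was possible without those batches, which hold much of he-ant. Between AGM and KT, edgeR called 0 of 6446 genes, with 423 at an unadjusted p under 0.05, and 11 genes without those batches. DESeq2 was not run on these comparisons.

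No gene passed the planned test of canonical against non-canonical cells. On sums per session, edgeR called 0 of 7054 genes, with 442 at an unadjusted p under 0.05, and DESeq2 called 0, with 67. On sums of 7 days, edgeR called 0 of 1879 genes, with 51 at an unadjusted p under 0.05, and DESeq2 called 0, with 54. A change of a log2 of 1 would mostly have been missed on sums per session, since 5.56% of such genes were recovered in simulated sums. On simulated sums per day 50% were recovered. Those simulations held no differences between days or sessions and left out the quasi-likelihood spread, so recovery in the data may be lower. Clusters 2 and 5 held 8.88% ± 8.63 of non-canonical and 7.92% ± 5.41 of canonical cells (exact permutation test, two-sided p = 0.688, n = 7). Of 19 clusters, 0 differed after adjustment, the smallest adjusted p being 0.742 (exact permutation tests, n = 7).

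Within 1 session, comparisons by the rule of size carried no test, and their counts cannot be set side by side as sizes of difference. The rule asks for the same direction in every pair of plates, and the number of plates differed. CHT and AKT had 6 and 6 plates, and CD41_Gata2b_CHT and CD41_Gata2b_AKT 2 and 2. The CHT against AKT comparison gave 431 genes, 128 higher in CHT and 303 lower, and without the richest 1% of wells 608, 129 higher and 479 lower. The CD41_Gata2b_CHT against CD41_Gata2b_AKT comparison gave 1485, with 620 higher and 865 lower, and runx1-cht against runx1-ant gave 1299, with 406 higher and 893 lower. The runx1-trunk cells gave 736 genes against runx1-ant and 190 against runx1-cht. The CHT against KT and AGM against KT comparisons gave 3941 and 2956, which fell to 1523 and 311 without the richest 1% of wells. The he-ant against runx1-ant comparison gave 1712, and 1215 without the richest wells. Non-canonical against canonical cells gave 233 genes in session 1, 95 higher in non-canonical and 138 lower. In session 2 this comparison gave 39 genes, 8 higher and 31 lower, and 4 without the richest 1% of wells. Non-canonical and canonical cells had 1 and 2 plates in session 1, and 4 and 5 in session 2. Genes whose intervals did not overlap numbered 262 in session 1 and 1732 in session 2, and 258 and 228 without the richest 1% of wells.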

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

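Apart from the tests of the depth of batch 19, of free RNA of the own batch and of shared barcodes in cluster 9, the tests in this part were chosen after their results or related values had been seen. Chance alone singles out about 1 in 20 groups of days, and 20 groups of 4 to 10 days were examined.

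A value lay far from the others in 4 of these groups. On day 6 of session 1, 3.09% of the KT cells fell in cluster 9. The other days of the AKT, KT or ant side had at most 0.935%, among the 9 days that also held CHT cells. AKT batches 13 and 14, sorted on a day without CHT cells, were outside this group and had 45.9% and 80%. On day 2 of session 2, 25.9% of non-canonical cells fell in cluster 6, against at most 11.1% on the other days. Canonical cells of that day had 33.3%, and the profile of cluster 6 was the closest in session 2 to wells with no cell (correlation 0.837). On day 8 of session 1, the median UMIs per cell were 3894 in canonical and 6877 in non-canonical cells, against at most 1982 and 1772 on the other days. The test of a different CHT change in CD41_Gata2b than in the first group called 1 gene, with a log2 difference of -2.26 (SE 0.327, edgeR adjusted p = 0.0457).

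Wells with no sorted cell passed the limits in 246 cases in session 1 and 140 in session 2, which drew attention because they hold signal outside the measured cells. These 386 wells resembled a richer well of the same barcode 47.9 percentage points more often than with shuffled barcodes (56.7% against 8.81%), so molecules of other batches counted through shared barcodes are a candidate source, and pairs of batches ranked alike in both sessions (Spearman rho 0.388 over 336 pairs, one-sided permutation p = 0.0001, the smallest these permutations can give). A property of the pool barcodes or of their handling remains open, while pool barcodes that differ by few bases are argued against, since pools 2 bases apart shared less (0.0248) than those 3 or 4 bases apart (0.0341, one-sided permutation p = 0.0015 over relabelled pool barcodes). Free RNA of the own batch also stays open for the 167 wells without such a likeness, whose median correlation with their batch was 0.57 against 0.596 for kept wells matched on UMIs. That value lay under the 25th percentile of unmatched kept wells (0.676), the bound written beforehand, but those wells hold more molecules, and the matched 25th percentile was 0.5. No biological explanation was tested.

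In session 2, 2 batches of he-ant cells differed, since batch 19 had 73.2% of 41 cells in clusters 2 and 5 (57.1 to 85.8) and batch 20 had 8.45% of 71. A lower depth of batch 19 is argued against, because wells of batch 20 in the same UMI range had 8.77% (2.91 to 19.3). Molecules of batch 14, which held runx1-cht cells, may account for the pattern, since 65.9% of the batch 19 wells lay in the cluster of the batch 14 well of the same barcode, against 33.1% with barcodes shuffled (one-sided permutation p = 0.0001, the smallest these permutations can give). Each of the 41 wells held fewer UMIs than its batch 14 well, with a median of 7.62%. No biological explanation was tested.

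In session 1, 137 of 150 cells of cluster 9 came from 1 plate of AKT cells. Free RNA in wells with little RNA of a cell stays open: the median of 3152 UMIs, against 2306 in other kept wells of the plate (two-sided permutation p = 0.6), mixes 2 batches. In batch 13, 45.9% of kept wells were in cluster 9, with medians of 1859 against 1669 UMIs (permutation p = 0.687), and in batch 14, where wells with no cell were richer (median 627 against 190 UMIs), 80% were, with 3765 against 7909 UMIs (permutation p = 0.0002, the smallest these permutations can give, but a bootstrap interval of the difference from -9991 to 112). These permutation tests compared mean log UMIs between wells of 1 plate, while the bootstrap interval is that of the difference of medians. The profile of cluster 9 was the closest in session 1 to wells with no cell (correlation 0.89, others 0.594 to 0.78) and its wells correlated slightly better with wells with no cell (0.621 against 0.602 and 0.702 against 0.696 in batches 13 and 14), yet their medians lay above the 95th percentile of those wells (768.8 and 2716 UMIs). Shared barcodes stay open, since the cells resembled a richer well of another batch 10.2 percentage points more often than with barcodes shuffled, between the bounds set beforehand, and whether the larvae of that day differed was not tested. These tests covered session 1 only. In session 2 cluster 9 held 90 cells, of which 58 were canonical and 27 non-canonical, with a median of 802 UMIs. Its profile there correlated with wells with no cell at 0.577 (others 0.54 to 0.837). It held 33 of 37 kept cells of batch 8, where 0% of wells resembled a richer same-barcode well. Batch 7, past the barcode limit, had 33.3%.

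Splits of the samples were counted beside each replicated comparison. Of 100 splits that swapped sides within days, 1, the real one, gave as many genes as the CHT comparison (3129), the highest other giving 2122 with 1 day swapped and 7 with 3 or more days swapped. A chance assignment of sides is therefore argued against. For CHT against AKT or KT alone, 1 of 32 splits reached 2001 genes and the highest other gave 1. That also argues against chance, but 1 of 32 is the smallest share that 6 days allow. Swaps within days cannot separate region from batch on the days whose sides lay in different batches. For canonical against non-canonical days, 64 of 64 splits gave at least the real count of 0, as any split must, so this count says nothing about chance. The highest other split gave 10 genes. For runx1-trunk against runx1-ant with no day block, on the 6 sums of all their days and not only of the 2 shared days, 10 splits are too few for a share under 0.05, with 177 genes in the real split, which alone (1 split) gave so many, and 0 in the highest other.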

How the results depend on the processing

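All alternatives on sorting days, and those that use genes differing between regions, batches past the barcode limit, the richest wells (except in cell shares), clusters near wells with no cell or the repeated plate were chosen after the data were seen, and the others before. Of 280 recomputed shares per population, 87 left their interval, yet in 11 of 11 settings clusters 2 and 5 were higher in every CHT population (at least 27.8%) than in AKT, KT, CD41_Gata2b_AKT and runx1-ant (at most 19.7%). The he-ant (20.9% as reported) and AGM shares were not compared here. At resolution 0.6 and in the clusterings without region genes no cluster took number 5, so that cluster 2 stands for both, and without region genes of a single ID cluster 4 stands for 3 and 4. The day differences of clusters 2 and 5 and of clusters 3 and 4 between CHT and the other side kept their direction in each alternative, and a p under 0.05 (exact permutation tests) except in clusters 3 and 4 without all region genes (-7.7 percentage points, p = 0.125, n = 9) or without those of a single ID (-12.9, p = 0.0625). Of the 12 and 14 numbers that then held cells, 2 and 0 differed by day after adjustment. Of 79 recomputed values of the 4 named genes, 78 stayed under 0.05 in the same direction, the exception being LL0000027897 with DESeq2. Thinning left fewer genes to test, so depth limits the counts of genes. The cause of each change was not tested.

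Cells kept in session 1 moved to 91.2% with 300 UMIs, 74.7% with 1000 and 82.6% above the batch background. In session 2 they moved to 59.5%, 36.8% and 38.7%, and to 52.9% without batches past the barcode limit. The share of clusters 2 and 5 in sessions 1 and 2 was 15.7% and 14.8% with genes standardised together, 19.2% and 18.3% at resolution 0.6, 23.1% and 24.2% at resolution 1.5, 15.9% and 13.7% without the genes that differed between regions within clusters, and 17.3% and 12.4% without all region genes. It was 19.5% in session 1 when clustered without batches past the limit and in session 2 23.9% with 1000 UMIs and 17.5% without region genes of a single ID. Clusters 3 and 4 held 28.8% in session 1 at resolution 0.6, 24.2% in session 2 with 1000 UMIs, 32.6% and 35.1% without all region genes, and 20.8% in session 1 without those of a single ID.

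Canonical against non-canonical gave 1 gene on session sums without the richest wells and the repeated plate, and on days 1 without the clusters near wells with no cell and 8 with no filter. Without the block that pairs the sides, CHT days gave 1946 genes of 5503 tested instead of 3129 of 8585, and 3048 on the same genes. On the same genes, runx1-trunk against runx1-ant gave 191 without the block and he-ant against runx1-ant 58. For canonical session sums and days, runx1-trunk against runx1-cht and AGM against KT, edgeR called 0 genes with or without it (8, 50, 249 and 358 at an unadjusted p under 0.05 without it). CHT days gave 788 genes after thinning and 2435 to 3152 with each day left out. AGM against KT gave 11 genes without batches past the limit. The canonical day difference in clusters 2 and 5 reversed to -1.34 percentage points when clustered without those batches (exact permutation test, two-sided p = 0.5, n = 6), and in clusters 3 and 4 it reached 8.22 without the genes that differed within clusters (exact permutation test, two-sided p = 0.0312, n = 7) and -6.64 without region genes of a single ID (exact permutation test, p = 0.0938, n = 7).

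By the rule of size, thinning gave 223 genes for CHT against AKT, 391 for CHT against KT, 77 for AGM against KT, 289 for CD41_Gata2b, 353 for runx1-cht and 173 for runx1-trunk against runx1-ant, 48 for runx1-trunk against runx1-cht, 378 for he-ant, and 43 and 6 for non-canonical against canonical in sessions 1 and 2. Without the richest wells, CHT against KT gave 1523 instead of 3941, AGM against KT 311 instead of 2956 and non-canonical against canonical in session 2 4 instead of 39. Leaving out the batches past the limit as well moved CHT against KT from 1523 to 1297, AGM against KT from 311 to 269, he-ant from 1215 to 1045, the session 2 canonical comparison from 4 to 10, CHT against AKT from 608 to 656, runx1-cht against runx1-ant from 1230 to 1724 and runx1-trunk against runx1-ant from 725 to 987.

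Leaving out a session or a day leaves no residual degrees of freedom in session sums or in comparisons of 2 days, so that alternative gave no value. Alternatives of named cell classes and gene lists were not run, since no ID had a name, and neither was a mitochondrial limit.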

Other observations

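All tests in this part were chosen after the data were seen. Cluster 17 held 13.8% of CD41_Gata2b_AKT cells (26 of 188, 9.24 to 19.6). The next highest shares were 3.12% of runx1-ant (2.05 to 4.55), 2.3% of CD41_Gata2b_CHT (0.63 to 5.78) and 1.62% of runx1-trunk cells (0.527 to 3.74), and AKT cells had 0.204%. Its cells were shallow, with a median of 739 UMIs in session 1 and 701.5 in session 2, and the difference between sides by day was -2.97 percentage points (0.638% against 3.61%), with an adjusted p of 0.119 (exact permutation test, n = 9). With a minimum of 1000 UMIs the side other than CHT fell to 1.32% and the difference to -0.777 percentage points.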
